A study of Mus musculus with 3 samples.

How the data were processed

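RNA of sorted embryonic mouse kidney cells was measured on 3 oligonucleotide arrays of the Mouse Compugen design, each read in 2 colours. Per the labels, channel 1 of every array held RNA of GFP+ cells and channel 2 RNA of GFP- cells from HoxB7-GFP transgenic kidneys at 15.5 days post coitum, both sexes pooled, with amplified RNA labelled through amino allyl groups, no common reference and no dye swap. Images were read with Imagene 5.5, per the labels. A Lowess curve of log ratio against log intensity, with 20% of the points in each local fit, adjusted the control channel, and control values below 10 were raised to 10, per the labels. The table titles describe the deposited values as filtered, and the rule of that filter is not given in the sources used here.

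The deposited values are log2 ratios. The base was settled from the numbers: 2 raised to the deposited value was a whole number of thousandths for 99.97% of values, within 0.01 of a thousandth, against 2.37% for base e. Mean log2 ratios of the arrays lay close to 0, with medians of -0.044, 0.094 and 0.062 on arrays 1, 2 and 3. The dyes of the channels are not stated. The direction used here, GFP+ over GFP-, rests on the wording of the titles and the order of the channels and is likely, since no source used here states the dyes. In that direction, Gata3 and Krt8 of the fixed ureteric epithelium list were positive on all 3 arrays, and Cd52, Mrc1 and Dcn of the fixed macrophage and stroma lists were negative on all 3. The authors' normalization was kept, and no raw intensities were analysed here, so signal over background could not be examined.

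The file held 22702 features, of which 883 were controls, blanks or other features that name no gene, and 4 of these had a value. Of the 21819 gene features, 15293 (70.1%) had no value on any array, 1105 had a value on 1 array, 1022 on 2 arrays and 4399 (20.2%) on all 3. Testing used the 4399 probes with values on all 3 arrays. The platform annotation listed 17408 probes, 17252 with 1 gene symbol and 156 with several, and left 5294 features without a gene. Symbols were updated through gene identifiers to those of the GRCm38.p6 RefSeq table, which matched 16566 probes; the other 842 kept their older symbol. Of the tested probes, 3987 had 1 gene symbol and gave 3915 genes, each the mean of its probes, while 412 probes with several genes or none entered the probe counts only. For the 69 genes with several tested probes, no pair of probes passed the threshold in opposite directions, and for 2 genes some but not all probes passed. No coordinates are given, since no genome build is named for the array.

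Each probe's mean log2 ratio was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, intercept only, two-sided), with Benjamini-Hochberg adjustment and a threshold of adjusted p below 0.05; genes were tested in the same way. The arrays form 1 group of 3 replicates. The labels do not say whether the arrays came from separate pools of embryos, so p-values measure only the spread between these arrays, which may be technical, and the number of arrays limits the precision. Without a dye swap, a dye effect specific to a gene cannot be separated from a difference between the cells. Errors are SDs over the 3 arrays.

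The groups, the test, the processing alternatives, the rule for named genes and 19 gene lists were chosen before the data were examined. Lists covered the ureteric tip, ureteric epithelium, collecting duct and urothelium, tight junction and desmosome, cap mesenchyme, early nephron, podocyte, proximal tubule, stroma, endothelium, erythroid cells, macrophages and leukocytes, nerve and glia, cell cycle, basement membrane, secreted signals and antagonists, immediate early and heat shock genes, ribosomal proteins, and oxidative phosphorylation. Lists with at least 5 measured members were tested with camera of limma at its preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 14 lists tested; camera with an estimated correlation and fry, a rotation test of whether a list's genes move one way on balance, were alternatives. The text names the 12 genes of highest and the 12 of lowest mean ratio past the threshold with the same sign on all 3 arrays, leaving out clone and model names, the 4 members of each list with the largest absolute mean, members past the threshold against their list's median, and 17 genes fixed in advance whatever their value. Any other gene is named as chosen after its values were seen.

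The test was checked on simulated data of 4399 probes on 3 independent arrays with 200 changed probes, in 20 runs. It found 54.4% of changes of log2 1 and 96.2% of changes of log2 2, and 5.11% of its calls were false. These rates do not cover arrays related as arrays 2 and 3 were (r = 0.879), with array 1 apart from them. The set test was run 50 times on 3915 simulated genes, independent of each other and of equal variance. It called 2.43% of unshifted lists at an unadjusted p below 0.05. With every stroma gene lowered by log2 1, it called that list in 100% of runs after adjustment. These set test rates do not cover lists whose genes vary together. In the data the estimated correlation ran from -0.191 for proximal tubule to 0.726 for cap mesenchyme. Alternatives covered centring, scaling and quantile normalization of the arrays, probes with values on at least 2 arrays, array weights, a robust prior, an ordinary one-sample statistic per probe, other thresholds, genes in place of probes, and leaving out each array in turn. Averaging arrays 2 and 3 to 1 replicate was added after the data were seen. Leaving out values at the control floor, planned for the case of a pile-up at the extremes, was not run, since no value was tied with another at either extreme. Floored features need not tie, however, and ratios alone do not identify them, so an effect of the floor on the large positive ratios stays open. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.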

Results

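The ureteric tree is the branching epithelium of the embryonic kidney that later forms the collecting ducts. Its cells were compared with all other kidney cells at 15.5 days post coitum (dpc) in mice carrying the HoxB7-GFP transgene, which marks the ureteric tree with green fluorescent protein. Cells were sorted by fluorescence into a GFP+ and a GFP- fraction, and amplified RNA of both was hybridised together on each of 3 arrays. The arrays gave log2 ratios, likely of GFP+ over GFP-, for 5179, 4980 and 6187 gene features, and 4399 probes had a value on all 3. Higher and lower are stated for that direction throughout.

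The ureteric epithelium and tight junction lists ranked higher in GFP+ cells, with 3 of 7 and 2 of 6 measured genes past the threshold, and the macrophage, stroma and cap mesenchyme lists ranked lower, with 5 of 7, 3 of 6 and 3 of 9. By camera of limma at its preset correlation, adjusted p was between 5.88e-12 and 0.00653 for these 5 lists. With an estimated correlation 0 of 14 lists passed (smallest adjusted p = 0.243, with 1 list at an unadjusted p below 0.05). For macrophages and tight junction the estimate (-0.151 and -0.0421) was below the preset 0.01, so higher correlation is not why they missed. For cap mesenchyme, ureteric epithelium and stroma the estimate was above it (0.726, 0.422 and 0.254), so their p-values at the preset may be too small. With 3 arrays this setting has few degrees of freedom, so missing the threshold under it neither shows nor excludes an effect of correlation there. Fry passed 4 of these 5 lists, cap mesenchyme being the exception. Gata3, a transcription factor needed for growth of the ureteric duct, was 5.10-fold higher in GFP+ cells (mean log2 ratio 2.35 ± 0.39, SD, n = 3 arrays), and Krt8, a keratin of simple epithelia, 4.22-fold higher (2.08 ± 0.28). S100a9, a calcium-binding protein abundant in neutrophils and monocytes, was 12.6-fold lower (-3.66 ± 0.44), and Cd52, a leukocyte surface glycoprotein, 7.15-fold lower (-2.84 ± 0.28). Wt1, a transcription factor of cap mesenchyme and podocytes, was 2.68-fold lower (-1.42 ± 0.37).

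By limma with Benjamini-Hochberg adjustment, 58 of the 4399 probes were higher and 68 lower in GFP+ cells, and all 126 had the same sign on the 3 arrays, as this test nearly requires. The difference exceeded 2-fold for 48 of the higher and 65 of the lower probes. Counted as genes, 54 of 3915 rose and 55 fell, and the smallest mean that passed was 0.89 in size. Without array 1 the probe counts were 1225 higher and 810 lower, without array 2 they were 53 and 82, and without array 3 they were 23 and 60. With arrays 2 and 3 averaged to 1 replicate, an alternative chosen after the data were seen, they were 32 and 68. Of these, 30 and 59 were among the 58 and 68. With array weights the probe counts were 1597 and 1015. So many probes passed without array 1 or with array weights that list counts under those settings say little about a list by themselves. With an ordinary one-sample statistic per probe, which shares no variance between probes, 1 probe was higher and 0 lower after adjustment. That 1 probe was not among the 58. At an unadjusted p below 0.05 by this statistic, 319 were higher and 213 lower. So few passed after adjustment that its counts for lists are given unadjusted.

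Kcnk1, a potassium channel of the tandem-pore family, had the highest mean ratio, 2.89 ± 0.44 or 7.42-fold (limma adjusted p = 0.00321), followed by the long noncoding RNA Pantr1 at 2.80 ± 0.03. Wfdc15b, a WAP-domain protein, reached 2.52 ± 0.16, and Fxyd4, a regulator of the sodium-potassium pump, 2.51 ± 0.48. The claudins Cldn7 (2.36 ± 0.27) and Cldn3 (2.03 ± 0.38), membrane proteins of tight junctions, rose together with S100g, a vitamin D-dependent calcium-binding protein (2.09 ± 0.02). Spint2, an inhibitor of serine proteases, rose by 1.97 ± 0.20 on the log2 scale. The 12 highest genes also held ccdc198 (2.25 ± 0.17) and Bex1 (1.93 ± 0.39), and adjusted p lay between 0.00321 and 0.0087 by limma for all 12.

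Among the genes lower in GFP+ cells, Penk, which encodes the precursor of enkephalins, had a mean of -2.90 ± 0.89, and Mgp, a matrix protein that inhibits calcification, -2.46 ± 0.62. Immune genes in this group, besides S100a9 and Cd52, included the chemokines Cxcl2 (-2.37 ± 0.17) and Ccl6 (-2.27 ± 0.23) and the Fc receptor gamma chain Fcer1g (-2.33 ± 0.56). Alas2, the erythroid enzyme that starts heme synthesis, had -2.15 ± 0.07, and the embryonic globin Hba-x -2.22 ± 0.38 over 2 probes; globins are alike in sequence, so signal could be shared between them. Tgfbi, a secreted matrix protein, had -2.30 ± 0.40, the tropomyosin Tpm2 -2.21 ± 0.17 and Abhd1 -2.35 ± 0.29. The limma adjusted p of the 12 lowest genes lay between 0.00321 and 0.0117.

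**Figure D1:**
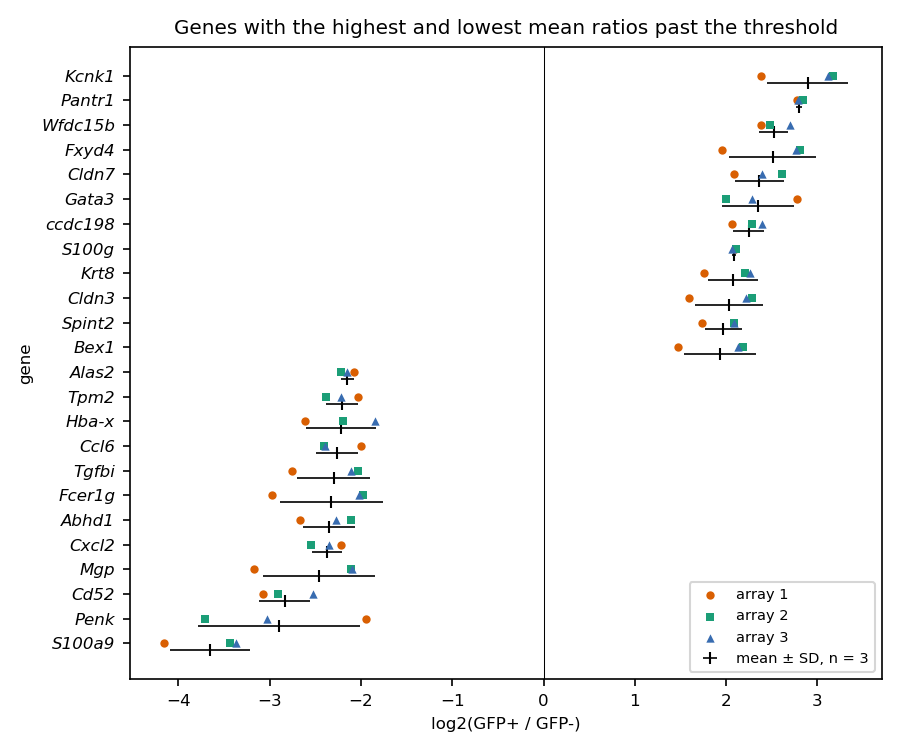
Log2 ratio of GFP+ over GFP- cells (horizontal axis) for the 12 genes of highest and the 12 of lowest mean ratio past the threshold (vertical axis); coloured symbols are arrays 1, 2 and 3, and the black tick with its bar is the mean with its SD over 3 arrays. Kcnk1 is highest at 2.89 and S100a9 lowest at -3.66. No gene has arrays on both sides of 0, since genes were chosen with the same sign on all 3.

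Of 33 ureteric epithelium genes, 7 were measured on all 3 arrays, and 3 of them rose: Gata3, Krt8 and Spint2. Gata2, a transcription factor related to Gata3, had 0.58 ± 0.34 and missed the threshold over all genes (limma adjusted p = 0.237), while 4 of the 7 passed when adjusted over the list alone. Means were positive for 4 of the 7 and negative for 3, Bcat1 (-0.14 ± 0.18), Grhl2 (-0.17 ± 0.26) and Rab25 (-0.042 ± 0.27), which did not pass and are named after their values were seen. The list's median was 0.58 (camera adjusted p = 0.00382), with adjusted p = 0.387 under an estimated correlation. Including genes with values on at least 2 arrays raised that median to 1.97. This added only Esrp1 (arrays 2 and 3) and Cdh16 (arrays 1 and 2), both named after their values were seen. Of the 20 ureteric tip genes only 3 were measured on all 3 arrays, too few for a set test. Spry1, an inhibitor of receptor tyrosine kinase signalling, rose (0.95 ± 0.11, limma adjusted p = 0.0386), also when adjusted over the list alone. Tfrc, the transferrin receptor, which is also in the erythroid list, had 0.38 ± 0.17, and the ETS factor Etv5 0.29 ± 0.37; neither passed. Without array 1, or with array weights, all 3 of these tip genes passed, and without array 3 none did by limma, Spry1 included (adjusted p = 0.342).

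In the tight junction and desmosome list, 6 of 25 genes were measured, and Cldn7 and Cldn3 rose, both also when adjusted over the list alone. The desmosomal plakophilin Pkp3 (0.52 ± 0.29) and the junction scaffold Tjp1 (-0.19 ± 0.36) did not pass. The list's median was 0.35 (camera adjusted p = 0.00653), with adjusted p = 0.387 under an estimated correlation and 0.143 by camera without array 1, where 3 members were higher and 1 lower; array weights gave 3 and 0. Of the 23 collecting duct and urothelium genes, 22 were on the array and 0 had values on all 3, so that list was not tested.

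Cap mesenchyme holds the nephron progenitors around the ureteric tips, and 9 of its 22 listed genes were measured. Crym (-1.72 ± 0.59), Wt1 and the homeobox gene Uncx (-1.20 ± 0.15) fell, and 6 members were lower when adjusted over the list alone. Cited1, a transcriptional coactivator of the progenitors, had -1.18 ± 0.47 and missed the threshold over all genes (limma adjusted p = 0.0557). The list's median was -0.98 (camera adjusted p = 1.99e-05), with adjusted p = 0.387 under an estimated correlation and 0.103 by fry. Array 1 gave the lowest median of the list (-1.17, against -0.58 and -0.91). Leaving array 1 out gave 2 higher and 6 lower members, as did array weights. There were 5 lower after centring, scaling or quantile normalization of the arrays, and also without array 2.

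None of the 7 measured early nephron genes of 17 passed in limma, nor when adjusted over the list alone, with 1 lower at an unadjusted p below 0.05 (1 higher and 1 lower, unadjusted, by the ordinary statistic). The list's median was -0.030 (camera adjusted p = 0.663), and its members of largest mean were the Notch target Hey1 (-0.56 ± 0.10), Sox4 (-0.52 ± 0.84), Irx1 (0.40 ± 0.41) and Ccnd1 (0.33 ± 0.09). Without array 1 the median was 0.079, with 2 higher and 3 lower, the counts also given by array weights, and without arrays 2 and 3 in turn it was -0.088 and -0.082. Tcf21, a transcription factor of podocytes and stroma, fell (-1.94 ± 0.35, limma adjusted p = 0.00742), alone among 3 measured podocyte genes and also when adjusted over the list alone. Vegfa (0.21 ± 0.03) and Podxl (0.02 ± 0.31) did not pass; the podocyte median was 0.017 and the mean -0.57, of opposite sign, and the list was too small for a set test; with array weights 1 podocyte gene was higher and 1 lower. Named after their values were seen, the podocyte list's Foxc2 (-1.80 and -1.75 on arrays 2 and 3) and Foxc1 (-1.36 on array 3 alone) were not tested. Of 5 measured proximal tubule genes, 0 passed in limma, over all genes or over the list alone, with 1 lower at an unadjusted p below 0.05 (0 unadjusted by the ordinary statistic). They included Ttr (-0.74 ± 0.45), Fxyd2 (0.30 ± 0.56), Ass1 (0.17 ± 0.66) and Hnf4a (0.15 ± 0.67). Their median was 0.15, camera pointed down (adjusted p = 0.871), and without array 1 the median was -0.22 with 1 higher and 2 lower, the counts also given by array weights, against 0.33 without array 2 and 0.24 without array 3.

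All 6 measured stromal genes of 31 had a negative mean. Mgp, the proteoglycan Dcn (-1.61 ± 0.26) and the fibrillar collagen Col5a2 (-1.10 ± 0.35) fell, and 4 members were lower when adjusted over the list alone. Vim, the mesenchymal intermediate filament, had -0.96 ± 0.44 and did not pass over all genes (limma adjusted p = 0.093). The stromal median was -1.03 (camera adjusted p = 1.99e-05), with adjusted p = 0.387 under an estimated correlation. Without array 1, or with array weights, 5 members were lower, and without array 3 there were 2, with Col5a2 lost (limma adjusted p = 0.249). In endothelium, 12 of 20 genes were measured and 0 passed in limma, over all genes or over the list alone, with 2 lower at an unadjusted p below 0.05 (also 2, unadjusted, by the ordinary statistic) and 4 lower with array weights. Its members of largest mean were Ramp2 (-0.96 ± 0.94), Emcn (-0.48 ± 0.37), the VEGF receptor Kdr (-0.42 ± 0.32) and Icam2 (-0.31 ± 0.07). Listed genes without a value on every array were not tested. They were Cdh5 (-2.08 and -1.28 on arrays 2 and 3) and, on array 3 alone, Pecam1 (-1.46) and Sox17 (-0.056). Cdh5 and Sox17 are named after their values were seen. The endothelial median was -0.19 (camera adjusted p = 0.0152), with adjusted p = 0.497 under an estimated correlation, 0.314 by fry and 0.213 by camera without array 1, where the median was -0.051; without array 2 it was -0.31.

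The macrophage and leukocyte list moved furthest, with a median of -1.86 over 7 measured genes of 20 and medians of -1.81, -1.88 and -1.88 on arrays 1, 2 and 3. Cd52, Fcer1g, the mannose receptor Mrc1 (-1.96 ± 0.28), the lysosomal membrane protein Laptm5 (-1.86 ± 0.04) and, named after its values were seen, the complement component C1qa (-1.56 ± 0.15) fell, and all 7 were lower when adjusted over the list alone. Camera gave an adjusted p of 5.88e-12, with adjusted p = 0.243 under an estimated correlation. Of 4 measured erythroid genes, Hba-x and Alas2 fell, also when adjusted over the list alone, while Hba-a1 (-0.33 ± 0.34) and Tfrc did not pass. The erythroid median was -1.24 without a set test, and without array 1, or with array weights, there were 1 higher and 3 lower members. The nerve and glia list had 1 measured gene, the neuronal tubulin Tubb3 (-0.18 ± 0.52), which did not pass over all genes (limma adjusted p = 0.75) or over the list alone.

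**Figure D2:**
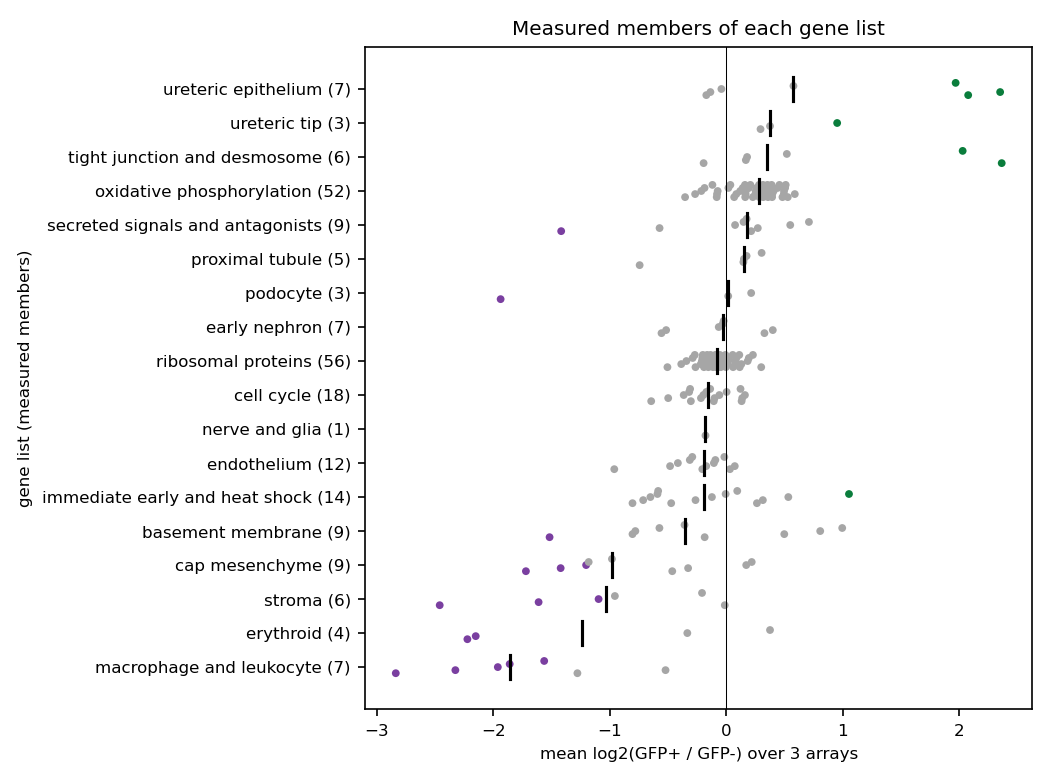
Mean log2 ratio of GFP+ over GFP- cells over 3 arrays (horizontal axis) for the measured genes of 18 lists (vertical axis, number of measured genes in brackets); each point is a gene, green if it rose, purple if it fell and grey if it did not pass, and the black tick is the list's median. The macrophage and leukocyte list has the lowest median (-1.86) and ureteric epithelium the highest (0.58).

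Among genes that do not mark a cell type, those of oxidative phosphorylation, the mitochondrial pathway of ATP synthesis, leaned upward. Of 52 measured genes, 44 had a positive mean, the list's median was 0.28, and camera gave an adjusted p of 0.000252, with adjusted p = 0.387 under an estimated correlation and 0.082 by fry. Single members did not pass in limma, over all genes or over the list alone (0 of 52; 8 higher at an unadjusted p below 0.05; 7 higher and 1 lower, unadjusted, by the ordinary statistic). The members of largest mean were Ndufa5 (0.59 ± 0.39), Ndufa6 (0.53 ± 0.15) and Ndufb2 (0.51 ± 0.31), subunits of complex I. Without array 1, 28 were higher and 4 lower, and with array weights 32 and 5. The 56 measured ribosomal protein genes had a median of -0.078 (camera adjusted p = 0.0529; 0.66 with an estimated correlation), and 0 passed in limma, over all genes or over the list alone, with 1 lower at an unadjusted p below 0.05 (1 higher, unadjusted, by the ordinary statistic). With array weights, 7 were higher and 27 lower, where 1597 and 1015 of all 4399 probes were. Rpl3 (-0.51 ± 0.21) and Rpl4 (-0.39 ± 0.47) had the lowest means. Camera passed this list after centring, scaling or quantile normalization of the arrays (adjusted p = 0.0441, 0.0315 and 0.0441) and without array 1 (0.0103; 6 higher, 8 lower), where the median was -0.20; without array 3 the median was 0.025. Across the 108 genes of these lists, which are not independent replicates, the ratios of array 1 ran against the mean of arrays 2 and 3 (Pearson's r = -0.393), whereas arrays 2 and 3 had r = 0.631.

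Of 18 measured cell cycle genes, 0 passed in limma, over all genes or over the list alone, with 2 lower at an unadjusted p below 0.05 (1 higher and 4 lower, unadjusted, by the ordinary statistic). The proliferation marker Mki67 (-0.64 ± 0.55) and the replication licensing factors Mcm4 (-0.50 ± 0.04), Mcm3 (-0.37 ± 0.12) and Mcm5 (-0.32 ± 0.12) had the lowest means. The cell cycle median was -0.16 (camera adjusted p = 0.0239), with adjusted p = 0.387 under an estimated correlation and 0.194 by fry, and camera did not pass it without array 1, 2 or 3 (0.213, 0.114 and 0.126), where the medians were -0.014, -0.24 and -0.22; without array 1, 1 member was higher and 5 were lower, and with array weights 1 and 6.

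Basement membrane genes went both ways. Nid1, which links laminin and collagen networks, fell (-1.52 ± 0.23, limma adjusted p = 0.0105), whereas the laminin chain Lama1 (1.00 ± 0.33, 0.0575), the collagen Col18a1 (0.81 ± 0.75) and Nid2 (-0.81 ± 0.21) did not pass over all genes. Of the 9 measured members, 3 were higher and 4 lower when adjusted over the list alone, and the median was -0.36 (camera adjusted p = 0.0623; 0.387 with an estimated correlation). Without array 1 the median was -0.23, with 2 higher and 4 lower (3 and 5 with array weights), and without array 2, 2 were higher and 1 lower. Among 9 measured secreted signals and antagonists, the Wnt antagonist Sfrp1 fell (-1.42 ± 0.15, limma adjusted p = 0.0105), and 2 were higher and 2 lower when adjusted over the list alone. Bmp7 (0.71 ± 0.28), Igfbp4 (-0.57 ± 0.24) and Igfbp2 (0.55 ± 0.20) did not pass over all genes. The list's median was 0.17, camera pointed up (adjusted p = 0.663) and fry down (0.992), and without array 1 there were 4 higher and 2 lower (5 and 2 with array weights). Among 14 immediate early and heat shock genes, the small heat shock protein Hspb1 rose (1.05 ± 0.23, limma adjusted p = 0.0367), also when adjusted over the list alone, but did not pass without array 3 (0.172). Fos (-0.81 ± 0.81), Jund (-0.71 ± 1.86) and Jun (-0.65 ± 0.74) did not pass, and the median was -0.19 (camera adjusted p = 0.324); without array 1 it was -0.025, with 4 higher and 4 lower (4 and 5 with array weights), and without array 2 it was -0.11.

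Most of the 17 genes fixed as reference points for the kidney's cell types had no value: 12 of them, Hoxb7, Ret, Wnt11, Calb1, Cdh1, Aqp2, Six2, Gdnf, Eya1, Foxd1, Col1a1 and Col3a1, were on the array without a value on any hybridisation. Krt8 and Wt1 were measured on all 3, Wnt7b had a value only on array 2 (-0.61) and Pecam1 only on array 3 (-1.46), and Hbb-b1 was not analysed here.

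Arrays 2 and 3 ran together and array 1 ran apart. Across the 4399 probes, which are not independent replicates, Pearson's r was 0.879 for arrays 2 and 3 (Spearman's rho 0.875), 0.274 for arrays 1 and 3 (0.0804) and 0.0765 for arrays 1 and 2 (-0.0832). The median absolute difference between arrays 2 and 3 was 0.14 on the log2 scale, against 0.55 for arrays 1 and 2 and 0.44 for arrays 1 and 3. Among the 552 probes with an absolute mean over 0.5, a selection that itself raises the correlation, r was 0.615, 0.764 and 0.938 for arrays 1 and 2, 1 and 3, and 2 and 3. No dyes were swapped, per the labels, and the labels do not say whether the arrays came from separate pools of embryos, so the SDs and p-values cover the spread between these arrays only.

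**Figure D3:**
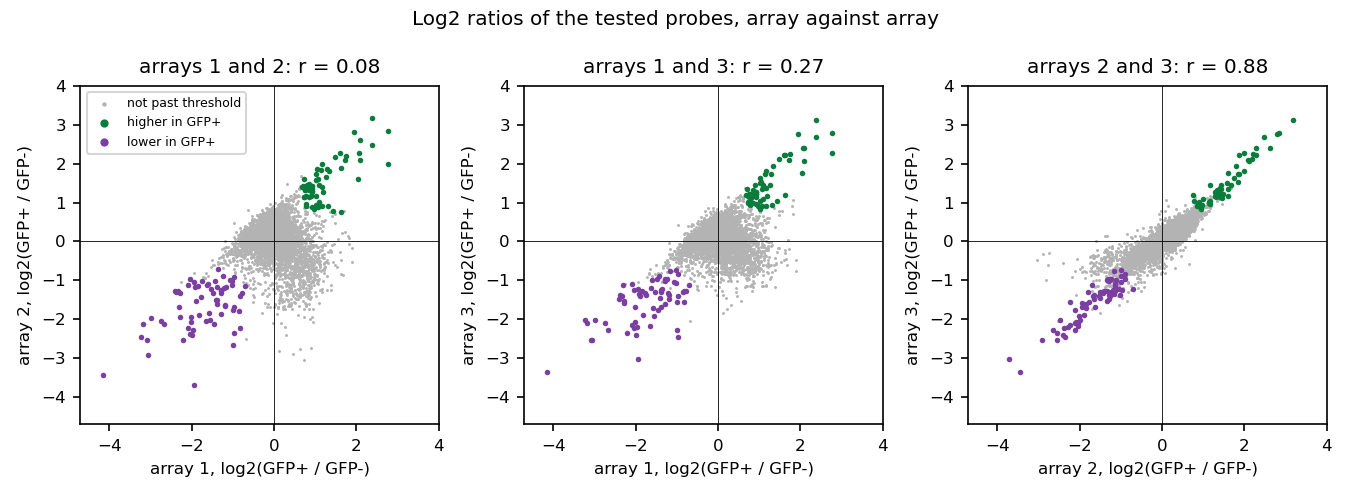
Log2 ratios of GFP+ over GFP- cells of the 4399 tested probes, 1 array on each axis, for the 3 pairs of arrays; green probes were higher and purple probes lower in GFP+ cells past the threshold, and grey probes did not pass. Arrays 2 and 3 lie along a diagonal (r = 0.879) and array 1 does so far less with array 2 (r = 0.0765) or array 3 (r = 0.274).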

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

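The tests of random noise, of a trend along feature number and of a dye effect on array 1 were chosen after the result was seen; those of sorted cell composition and of turned array signs were set before it.

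Data outside the comparison held further large ratios: 1022 gene probes had values on exactly 2 arrays and were not tested. Control features reached at most 0.41 in absolute log2 ratio, but only 4 of 883 had a value, so this is a rough mark. Of the 1022 probes, 481 had opposite signs on their arrays. Above 0.41 on both arrays lay 54 in the GFP+ direction and 102 in the GFP- direction. Of these, 44 of the 54 and 95 of the 102 were measured on arrays 2 and 3, which ran together over all probes (r = 0.879), so their agreement is weak evidence; among the 142 probes of arrays 1 and 2, 3 were higher, 2 lower and 109 of opposite signs, and among the 498 of arrays 1 and 3, 7, 5 and 321. Beyond 2 on the log2 scale on both arrays, genes named after their values were seen were Rprm (3.55 and 3.58) and the epithelial splicing regulator Esrp1 (2.98 and 3.11), both on arrays 2 and 3, and the kidney cadherin Cdh16 (2.55 and 3.19, on arrays 1 and 2) on the higher side. On the lower side, all on arrays 2 and 3, they were the Fc receptor Fcgr3 (-4.46 and -3.24), the embryonic globin Hbb-y (-2.59 and -2.57), Cd83 (-2.34 and -2.40) and Clec4a3 (-2.22 and -2.20).

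Array 1 stood apart from arrays 2 and 3 (r of 0.0765 and 0.274 with them, against 0.879 between them). Random spot noise is argued against for 108 ribosomal protein and oxidative phosphorylation genes. Across them, the ratios of array 1 ran against the mean of arrays 2 and 3 (r = -0.393, 95% bootstrap interval over genes -0.548 to -0.211), while arrays 2 and 3 had r = 0.631, and noise gives no opposite order. Over all 4399 probes, Spearman's rho of array 1 was -0.0832 with array 2 and 0.0804 with array 3, so noise stays open for other probes. A trend along feature number is argued against as well, since 50 bins of it held 1.88% of the variance of the deviation, barely above the highest of 100 permutations (1.77%). An effect of the dyes on single genes, with the dyes laid the other way round on array 1, may be a candidate explanation because it needs that negative r, but the labels name no dye swap. A different makeup of the sorted cells, the biological explanation, stays open. Different probes of the same gene had r = 0.0448 for the deviation over 69 genes (interval -0.219 to 0.287). This was below the 0.5 set beforehand in its favour, yet the interval did not stay under the 0.2 set to exclude it. For the mean of the 3 arrays the same probe pairs had r = 0.633 (interval 0.11 to 0.829). A signal that probes do share thus also missed an interval above 0.5, so the test cannot decide. A low r between probes of the same gene is also what random noise on array 1 would give.

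The count of 126 probes was set against turning the sign of 1 array. Only 1 of the 4 sign patterns, the deposited one, gave a count as large, and the highest other gave 0, but 4 patterns are too few for a share below 0.05.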

How the results depend on the processing

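Averaging arrays 2 and 3 to 1 replicate was the only alternative chosen after the data were seen; it gave 32 higher probes (30 of them among the 58) and 68 lower. Centring, scaling, quantile normalization, values on at least 2 arrays, a robust prior, a further 2-fold requirement and counting genes kept both counts within 1.5 times of 58 and 68. Array weights (0.142, 1.38 and 5.1 for arrays 1, 2 and 3) gave 1597 higher and 1015 lower; the cause was not tested. The ordinary one-sample statistic gave 1 and 0 (319 and 213 at an unadjusted p below 0.05), and the 1 was not among the 58. Adjusted p below 0.1 gave 89 higher, and below 0.01 gave 15 higher and 24 lower. Leaving out 1 array gave between 23 and 1225 higher and between 60 and 810 lower, the highest without array 1. Of the 36 named genes past the threshold, the ordinary statistic kept 0, leaving out array 3 kept 33 (Spry1, Col5a2 and Hspb1 lost), and every other alternative run on them kept 36. Of the 44 named genes that missed it, 36 passed with array weights, 31 without array 1 and at most 4 under any other alternative. Among probes with an absolute mean over 0.5, r rose to 0.615 for arrays 1 and 2 and 0.764 for arrays 1 and 3, by selection.

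No list that camera passed changed direction. Among lists that did not pass, the median changed sign without array 1 for proximal tubule (-0.22) and early nephron (0.079) and without array 3 for ribosomal proteins (0.025). With an estimated correlation camera passed none: medians are unchanged by construction at 0.58 (ureteric epithelium), 0.35 (tight junction), -0.98 (cap mesenchyme), -1.03 (stroma), -0.19 (endothelium), -1.86 (macrophages), -0.16 (cell cycle) and 0.28 (oxidative phosphorylation), with adjusted p from 0.243 to 0.497. Fry did not pass cap mesenchyme (-0.98), endothelium (-0.19), cell cycle (-0.16) and oxidative phosphorylation (0.28). With values on at least 2 arrays, 15 lists were tested with cameraPR, a form of camera run on the genes' limma statistics. Cell cycle (-0.18) missed the threshold there (cameraPR adjusted p = 0.0576), where both the test and the probes differed from the main setting. The probe of smallest variance per gene brought basement membrane (-0.43, 0.0371) and ribosomal proteins (-0.078, 0.0479) past it, as did centring (-0.12), scaling (-0.10) and quantile normalization (-0.10) for ribosomal proteins. The cause of these changes was not tested. With 3 arrays, camera with an estimated correlation has few degrees of freedom, so its failures do not by themselves show correlation between genes. Nor do they exclude it for cap mesenchyme, ureteric epithelium, endothelium and stroma, where the estimate was 0.726, 0.422, 0.327 and 0.254 against the preset 0.01. Leaving out 1 array gave medians between 0.40 and 0.45 for tight junction, -0.31 and -0.051 for endothelium, -0.24 and -0.014 for cell cycle, and -0.20 and 0.025 for ribosomal proteins. The alternative without values at the control floor was not run, and its effect stays open. Signal over background, which limits dim probes, was not analysed here.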

Other observations

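All genes in this part were picked after their values were seen, and no further tests were run on them as groups.

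Further genes rose in GFP+ cells by limma with Benjamini-Hochberg adjustment. The membrane-anchored serine protease Prss8, an activator of the epithelial sodium channel, rose by 1.47 ± 0.20 (SD, n = 3 arrays, limma adjusted p = 0.0105), and the WAP-domain gene Wfdc2 rose by 1.91 ± 0.31, next to its relative Wfdc15b. The p38 kinase Mapk13 (1.63 ± 0.31), Bspry (1.81 ± 0.22) and the planar polarity cadherin Celsr1 (0.89 ± 0.10) rose, as did the ephrin Efnb2 (0.91 ± 0.12) and the Eph receptor Ephb3 (1.16 ± 0.25). The microsomal glutathione transferase Mgst1 (1.66 ± 0.44) and the glutathione transferase Gstt2 (1.47 ± 0.39) rose. Among 10 measured genes with symbols beginning in Gst, a count that leaves out Mgst1, Gstt2 was the 1 that passed. Of 10 measured Hox genes, Hoxd4 (1.37 ± 0.30) and Hoxb3 (0.94 ± 0.09) rose and Hoxa5 fell (-0.996 ± 0.243).

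Apoe, the apolipoprotein secreted by macrophages among other cells, had a mean log2 ratio of -2.14 ± 0.16 (SD, n = 3 arrays, limma adjusted p = 0.00321), and its receptor Lrp1 -1.40 ± 0.11, whereas Vldlr, another Apoe receptor (1.19 ± 0.43), Apoc1 (1.34 ± 0.26), Stard10 (1.07 ± 0.29) and the fatty acid-binding protein Fabp3 (1.06 ± 0.05) rose. The matrix glycoprotein Sparc fell (-1.16 ± 0.17). The imprinted genes Meg3 (-1.31 ± 0.47) and Cdkn1c (-0.92 ± 0.16), expressed from the maternal copy, both fell. Outside the fixed immune list, genes that fell included Ccl2 (-1.71 ± 0.14), Tlr2 (-1.08 ± 0.05) and Lst1 (-1.78 ± 0.33). Of 7 measured chemokines 3 fell and 1, Ccl21c (0.92 ± 0.03), rose; its gene has near-identical copies that share probe signal.

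The control features say little by themselves about array 1. All 3 control features with values on every array had the opposite sign on array 1: -0.40 against 0.41 and 0.39, -0.38 against 0.36 and 0.38, and, for a blank, 0.17 against -0.38 and -0.24. Those besides the blank bear the same control number, so the 3 are not independent. Mixed signs were also common in general, since 36% of the 4399 tested probes had the same sign on all 3 arrays.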
